A study of Mus musculus with 6 samples.

How the data were processed

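Total RNA of 6 mouse heart samples, extracted with Trizol and prepared with a TruSeq RNA kit per the labels' protocols, was grouped by the shRNA that the labels name, with 3 libraries each. One deposited table holds 55359 genes with their identifier, name, chromosome, start, end and strand. Its raw counts per gene are as the authors deposited them, per the file headers, and are not scaled to depth. Its FPKM values were computed by the authors, per the file headers, and list genes without counts at 0.0001. Bowtie 0.12.2 and the mouse build mm8 are named in the submitters' processing notes, with no role stated. The counting tool, the annotation version and the build of the table's coordinates are not given in the sources used here. Of 52083 gene identifiers shared with GENCODE M21, 1423 had the start and end listed there and 48532 the length, so coordinates are given as the table gives them, no build is named, and no sequence was taken from a reference. The counting is not stated to use strand, so reads of overlapping genes on either strand cannot be told apart.

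The design fixed before the data were examined named limma on log2(FPKM + 0.5) for a table without counts and edgeR if counts were given. Counts were given, so the test was the two-sided quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filter of filterByExpr and Benjamini-Hochberg adjustment, and 20489 genes were tested. The named genes, the gene lists and most alternatives were fixed at the same time, and 4 alternatives were added after seeing the data. A gene passed at an adjusted p under 0.05. CPM are counts-per-million values on the TMM-scaled library size, and means carry the SD over 3 libraries. A log2 fold change is shYthdf2 minus shNC and carries a standard error derived from the F statistic, with a 95% interval. A fold against a group with 0 counts in all libraries was computed against the floor of 3 counts per library, as a lower bound. The floor covers the counting error of reads only, and as reads were not marked by molecule it does not bound the sampling of molecules. It leaves out the spread between libraries, which the interval includes. Tested genes held 99.9% to 99.97% of the counts of each library. For single genes an exact permutation test of the 6 values was run, which cannot go below p = 0.1.

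Genes were named by a fixed rule: Ythdf2 and Slc7a11 always, then per direction up to 12 genes whose groups do not overlap, first by size of change among those past the threshold and then by smallest p among those at an unadjusted p under 0.05 and at least 2-fold, predicted gene names left out. In each described list the members named come from the 4 with the smallest p, and 12 genes of ferroptosis, cardiac stress and the YTHDF family were always included. Non-overlap was judged on FPKM. Of the 49 gene lists fixed, for pathways, cell types and blood, 48 had at least 5 tested members, and the replication-dependent histones were not tested because their symbols did not match the table. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 48 lists, and again with an estimated correlation, with ranks and with fry. Under the other alternatives camera was run at the preset correlation only. The mean level of a list in a library is the mean over members of the log2 CPM less the gene's mean over the 6 libraries.

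The procedure was tested on simulated counts for 20489 genes with the means, library sizes and dispersions of these libraries, 3 against 3, with 50 genes changed at each size. It recovered 2%, 42%, 70% and 78% of the genes changed 2-, 4-, 8- and 16-fold, with 7 false calls. At 0.1 times the estimated dispersion it recovered 72%, 90%, 96% and 98%, with 20 false calls. The simulated libraries were independent of each other, without the close pair and the other structure seen among the real ones. The recovery in the real libraries may therefore differ. The common biological coefficient of variation of the libraries was 48.2%.

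Alternatives that changed 1 choice of the main fit were looser and stricter filters, other scalings and a replicate block. Each library was also left out in turn, with the filter run again, so that 21245 to 21927 genes were tested instead of 20489. DESeq2 1.42.0 changed the test and its scaling. The limma alternatives changed the test and the scale together. They were limma on quantile-normalized log2 CPM, and limma on log2 FPKM with pseudocounts of 0.1 and 1, without trend, with array weights or with robust empirical Bayes. Added after seeing the data were limma with trend on log2(FPKM + 0.5), robust quasi-likelihood, shYthdf2 1 and 2 summed, and 48 rows that overlap a row of the same name summed onto it. Transcript-level testing was not run because the rows are genes. No sample was left out.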

Results

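RNA from mouse hearts was sequenced after ischemia-reperfusion (I/R), an injury in which blood flow to the heart is stopped and then restored. C57BL/6 mice, a common inbred strain, had received by tail vein an AAV9 vector, an adeno-associated virus that reaches heart muscle, carrying either a short hairpin RNA (shRNA) against YTHDF2 or a negative control shRNA (NC). The construct had a GFP gene and the cTNT promoter, which is active in cardiomyocytes. Surgery followed 4 weeks later, with 45 min of ischemia and 24 h of reperfusion. There were 6 libraries of total RNA, 3 labelled NC shRNA (shNC 1 to 3) and 3 labelled YTHDF2 shRNA (shYthdf2 1 to 3). All came from hearts after I/R. The deposited table held 76026601, 75632483 and 67023813 counts for shNC 1, 2 and 3. It held 71121131, 76428893 and 77561552 counts for shYthdf2 1, 2 and 3. At this depth a gene with 0 counts has an upper limit of 3 counts, a counts-per-million (CPM) value of 0.0388 to 0.0443 depending on the library. The labels do not say whether the replicates were separate animals, so p-values measure only the spread between these samples, which may be technical. The comparison asks how an shRNA against YTHDF2, a reader protein that binds N6-methyladenosine (m6A) in RNA, changes the transcripts of the injured heart. The title of the series names SLC7A11 and ferroptosis, an iron-dependent cell death driven by lipid peroxidation.

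Ythdf2 was not lower in the libraries labelled YTHDF2 shRNA. The gene (ENSMUSG00000040025, chromosome 4, 131912223 to 131939614 on the minus strand, in the coordinates of the deposited table) had 20.7, 24.3 and 27.0 CPM in shNC 1, 2 and 3 and 25.1, 25.6 and 32.7 CPM in shYthdf2 1, 2 and 3. The means were 24.0 ± 3.16 CPM (SD, n = 3) and 27.8 ± 4.28 CPM (SD, n = 3), and the exact two-sided permutation test gave p = 0.4. The log2 fold change was 0.21 ± 0.20 (SE), with a 95% interval from -0.25 to 0.68 and an adjusted p of 0.976 in the edgeR quasi-likelihood test. The targeted transcript therefore does not separate the labels, and each direction below is between libraries labelled YTHDF2 shRNA and libraries labelled NC shRNA. The paralogous readers Ythdf1 (log2 fold change 0.11 ± 0.19 SE, turning to -0.0025 without shYthdf2 3) and Ythdf3 (-0.23 ± 0.18 SE) did not pass the test either.

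Slc7a11, which encodes the cystine/glutamate antiporter that supplies cystine for glutathione, was high in shYthdf2 1 and 2 but not in shYthdf2 3. The gene (ENSMUSG00000027737, chromosome 3, 49846975 to 50398063 on the minus strand) had 1.57, 1.17 and 2.27 CPM in the shNC libraries and 10.8, 12 and 1.01 CPM in shYthdf2 1, 2 and 3. The log2 fold change was 2.25 ± 0.81 (SE), with a 95% interval from 0.36 to 4.15, and the adjusted p in edgeR was 0.976. The exact permutation test of the 6 values gave p = 0.4, where 0.1 is the smallest two-sided p that 3 against 3 libraries can give. Without shYthdf2 3 the log2 fold change of Slc7a11 was 2.78 and the adjusted p 0.285. On the log2(FPKM + 1) scale it was 0.42, and the adjusted p over all alternatives ran from 0.0528 to 1.00. The libraries shYthdf2 1 and 2 were the most alike of all pairs, and the labels do not say whether they share an animal or an RNA pool.

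**Figure D1:**
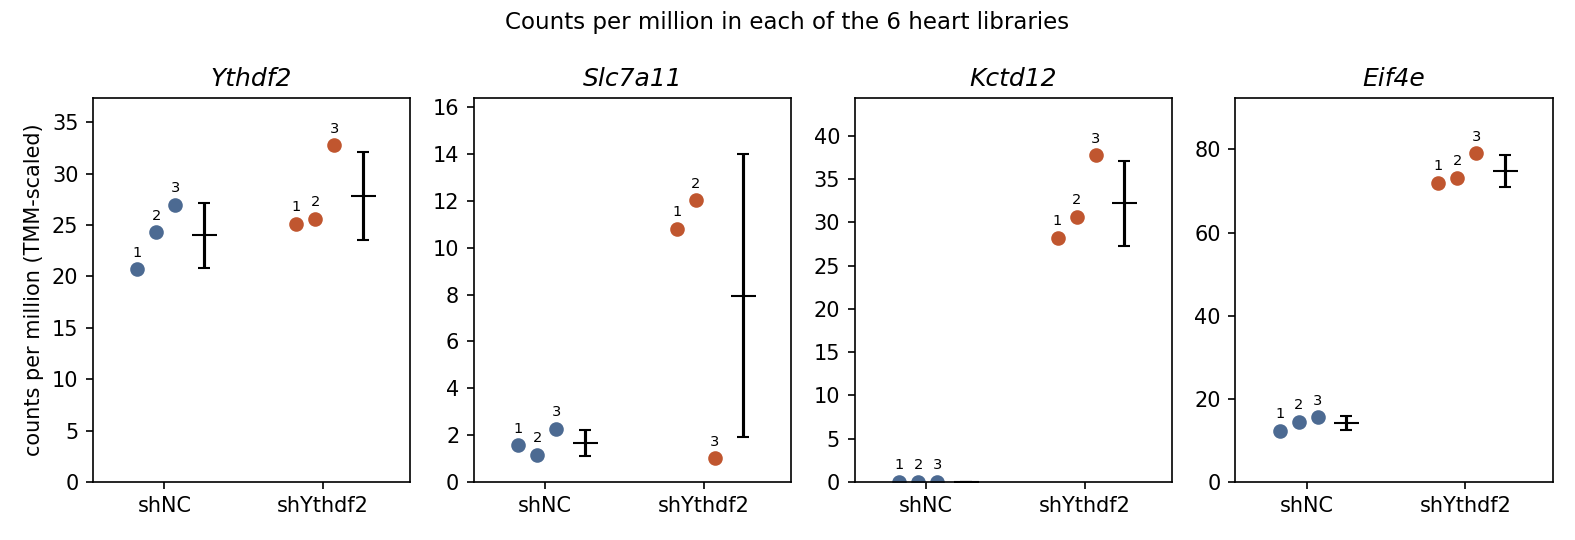
CPM (linear axis, TMM-scaled) of Ythdf2, Slc7a11, Kctd12 and Eif4e in the 3 shNC and 3 shYthdf2 libraries, each point a library with its replicate number, and beside them the mean with its SD. Ythdf2 overlaps between the groups, Slc7a11 is at 10.8 and 12 CPM in shYthdf2 1 and 2 and at 1.01 CPM in shYthdf2 3, and Kctd12 and Eif4e are separated.

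Across the 20489 genes tested, 2 rose in the libraries labelled YTHDF2 shRNA and 0 fell. Kctd12, an auxiliary subunit of GABA-B receptors (ENSMUSG00000098557, chromosome 14, 103214017 to 103220073 on the minus strand), had 0 counts in each shNC library and 28.3, 30.6 and 37.7 CPM in shYthdf2 1, 2 and 3. Its mean was at least 778-fold higher against the floor of 3 counts per library (edgeR adjusted p = 0.00877). Eif4e, the cap-binding subunit of the translation initiation complex (ENSMUSG00000028156, chromosome 3, 138231940 to 138265457 on the plus strand), rose 5.29-fold, from 14.1 ± 1.67 CPM (SD, n = 3) to 74.7 ± 3.85 CPM (SD, n = 3). Its log2 fold change was 2.40 ± 0.18 (SE), with an edgeR adjusted p of 0.0203. For each of these 2 genes all 3 shYthdf2 libraries lay above all 3 shNC libraries. No call survived with any 1 shYthdf2 library left out. The adjusted p of Kctd12 was 0.0960, 0.107 and 0.0793 without shYthdf2 1, 2 and 3, and that of Eif4e was 0.151, 0.168 and 0.0793. The difference of Eif4e stayed as large, at a log2 fold change of 2.43, 2.42 and 2.36. For Kctd12 the 0 counts in shNC cannot change when an shYthdf2 library is left out. Eif4e was also lost without shNC 1 (adjusted p = 0.0614) and shNC 2 (adjusted p = 0.166). Over all alternatives the adjusted p ran from 2.7e-25 to 0.491 for Kctd12 and from 3.8e-30 to 0.491 for Eif4e. The count of genes past the threshold was 1 without shNC 1, 1 without shNC 2, 211 without shNC 3 (137 higher), 53 with DESeq2 (39 higher) and 908 with limma array weights on FPKM.

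Below the adjusted threshold, 443 genes had an unadjusted p under 0.05 and at least a 2-fold difference, 223 higher and 220 lower, and 111 of them were under 1 CPM in both groups. The higher share of 50.3% was not stable over the alternatives. It was 40.5% without shYthdf2 2, 61.5% without shNC 3, 43.2% with DESeq2, 72.8% with limma on log2(FPKM + 1) and 76.0% with array weights. The 748 genes at an unadjusted p under 0.05 were fewer than the 1024 expected by chance. The groups did not overlap in 1860 genes, 9.08% of those tested, where chance gives 10%. Without shNC 3 the 2-fold set held 1657 genes, and with DESeq2 it held 666.

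Among named genes that were higher without passing, Alg2, a mannosyltransferase of N-glycan assembly, was 6.31-fold higher (1.78, 1.37 and 1.5 CPM against 8.63, 9.55 and 11.2 CPM, adjusted p = 0.0971). Etv5, an ETS-family transcription factor, was 21.6-fold higher (1.30, 0.384 and 0.619 CPM against 14.2, 15.0 and 20.6 CPM, adjusted p = 0.170). Ap1g1, a subunit of a clathrin adaptor, was 2.45-fold higher (adjusted p = 0.516) and the adhesion receptor gene Adgrl1 2.19-fold (adjusted p = 0.660). Dnajb4, a co-chaperone of HSP70, was 2.81-fold higher (adjusted p = 0.833), and the tetraspanin gene Cd151 2.11-fold (adjusted p = 0.963). Pphln1, Kctd17 and Tnfrsf9 were 2.67-, 2.66- and 4.85-fold higher (adjusted p = 0.976 each). A row named Septin2 (ENSMUSG00000116048) had 0 counts in the shNC libraries and 24.1, 10.4 and 181 CPM in the shYthdf2 libraries (adjusted p = 0.976). It overlaps another Septin2 row (ENSMUSG00000026276) on the same strand. That row held 1067, 1046 and 5401 counts in shNC and 8531, 10626 and 623 in shYthdf2, so the 2 rows can split reads and the zeros are uncertain. The summed rows held 1067, 1046 and 5401 counts in shNC and 10274, 11429 and 14393 in shYthdf2, with a log2 fold change of 2.25 ± 0.63 (SE) and an adjusted p of 0.976. With DESeq2 all 10 of these genes, Septin2 by its first row, passed (adjusted p from 1.1e-19 to 0.0027). Etv5 also passed with limma without trend (adjusted p = 0.0442) and with robust empirical Bayes (adjusted p = 0.0487).

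Among named genes that were lower without passing, Exosc6, a subunit of the RNA exosome, was 17.2-fold lower (5.35, 5.31 and 16.6 CPM against 0.291, 0.659 and 0.632 CPM, adjusted p = 0.660). The fold depended on shNC 3: without it the log2 fold change of Exosc6 was -3.33 instead of -4.10, and the gene passed in edgeR (adjusted p = 0.0374). The kinase gene Camk2b was 4.18-fold lower, Cep43 3.41-fold, the clock gene Arntl 2.3-fold, the glutathione transferase gene Gstp2 2.26-fold and Depp1 2.01-fold (adjusted p = 0.976 each). Dio1, Clec4f, Zfp968-ps, Dlx6os1 and Arhgap20os had 0 counts in all 3 shYthdf2 libraries and under 1 CPM in each shNC library. They were at least 13-, 9.78-, 12-, 8.30- and 4.60-fold lower at the floor of 3 counts per library (adjusted p = 0.976 each). With DESeq2, Exosc6, Camk2b, Arntl, Gstp2, Depp1, Dio1, Clec4f, Zfp968-ps and Dlx6os1 passed (adjusted p from 7.3e-09 to 0.0326), and Cep43 and Arhgap20os did not.

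Of the 48 gene lists tested, 19 passed camera at a preset correlation between genes of 0.01, 13 of them higher in the libraries labelled YTHDF2 shRNA and 6 lower. None of these calls held with an estimated correlation, where the adjusted p of the 19 lists lay between 0.761 and 0.769. Lists of low estimated correlation lost their call too, such as ferroptosis promotion (0.051) and smooth muscle and pericyte markers (0.085). With the correlation estimated from 6 libraries that test has little power, so a lost call does not show that a list was unchanged. Platelet transcripts and inflammatory mediators were among the lists called higher, and respiratory chain genes and erythroid transcripts among those called lower. In 7 of the 19 lists the mean furthest in the called direction was that of a control, shNC 3. For the lists called lower, it was -0.47 for the respiratory chain, -1.12 for erythroid transcripts, -0.90 for fatty acid oxidation, -0.59 for the tricarboxylic acid cycle and -0.53 for ventricular markers, in log2 units around the mean of the 6 libraries. For those called higher, it was 0.69 for the matrix list and 0.93 for cardiac stress. The platelet and neutrophil means were lowest of the 6 libraries in shYthdf2 3. The directional test of fry called 0 lists (lowest adjusted p = 0.699). Over all genes tested, 0 members of any list passed in edgeR and 6 in DESeq2. The count of lists was 9 without shNC 1, 11 without shNC 2 and 12 without shYthdf2 2. With shYthdf2 1 and 2 summed it was 15. That ended the calls of the neutrophil (adjusted p = 0.236), NF-kappaB (0.0648), tricarboxylic acid cycle (0.252), ferroptosis marker (0.106) and interferon lists (0.154).

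Platelet transcripts were higher in 11 of 11 members, with a median log2 fold change of 2.69 (camera adjusted p = 2.3e-10, and adjusted p = 0.761 with an estimated correlation). Adjusted over the list alone, 5 members passed. The transcripts were high in shYthdf2 1 and 2 and not in shYthdf2 3, where the list's mean lay 1.59 log2 units under the mean of the 6 libraries (-1.59, against 2.10 and 2.18 in shYthdf2 1 and 2). Ppbp, a platelet chemokine, had 6.16, 4.59 and 6.86 CPM in shNC and 40.01, 41.8 and 8.55 CPM in shYthdf2. Pf4, platelet factor 4, had 28.8, 23.2 and 37.5 CPM against 71.8, 71.7 and 39.1 CPM. Cytokines and chemokines were higher in 28 of 34 members, with a median of 0.53 (camera adjusted p = 3.2e-07, and adjusted p = 0.761 with an estimated correlation). Adjusted over the list alone, 1 passed. That member was Ccl3, a chemokine that attracts monocytes and neutrophils, at 0.635, 0.738 and 0.817 CPM in shNC and 7.47, 7.36 and 1.72 CPM in shYthdf2. Cxcl2, a neutrophil attractant, had 5.52, 12 and 9.35 CPM in shNC and 59.5, 57.3 and 6.20 CPM in shYthdf2. The cytokine mean was -0.22 in shYthdf2 3, under the 0.14 of shNC 3. At the preset correlation the calls of the platelet and cytokine lists held with any 1 library left out, with medians from 2.05 to 3.13 and from 0.31 to 1.18. The estimated correlation between members was 0.89 and 0.18. Leaving out shYthdf2 1 or 2 keeps the other of this closest pair, so these calls do not show that the rise holds beyond it.

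Neutrophil markers were higher in 21 of 25 members (median 0.75, camera adjusted p = 0.0019), and NF-kappaB targets and adhesion genes in 20 of 22 (median 0.25, adjusted p = 0.0023). Immediate early genes, the first genes induced by a stimulus, were higher in 19 of 23 (median 0.27, adjusted p = 0.00092). With an estimated correlation these had an adjusted p of 0.769, 0.761 and 0.769. The neutrophil list's mean lay at 0.95 in shYthdf2 1, at 0.95 in shYthdf2 2 and at -1.16 in shYthdf2 3, on the log2 scale around the mean of the 6 libraries. The NF-kappaB mean was -0.36 in shYthdf2 3, against -0.43, -0.04 and -0.23 in shNC 1, 2 and 3. The immediate early mean was -0.16 in shYthdf2 3 and 0.36 in shNC 3. The neutrophil call was lost without shNC 1, shYthdf2 1 or shYthdf2 2 (highest adjusted p = 0.310). That of the NF-kappaB list was lost without shNC 1 or shYthdf2 2 (highest adjusted p = 0.114) and that of the immediate early list without shNC 1 (adjusted p = 0.0513). With 1 library left out the medians ran from 0.44 to 1.16 for neutrophil markers, 0.10 to 0.47 for the NF-kappaB list and 0.17 to 0.68 for immediate early genes.

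Nuclear-encoded respiratory chain genes were lower in 49 of 50 members, with a median log2 fold change of -0.66 (camera adjusted p = 5.6e-15, and adjusted p = 0.761 with an estimated correlation). Ndufb3, a subunit of complex I, had 301, 409 and 168 CPM in shNC and 179, 172 and 145 CPM in shYthdf2, so that shNC 3 lay near the shYthdf2 libraries. The call held at the preset correlation with any 1 library left out, with a median from -0.93 to -0.31, while the estimated correlation was 0.91. Mitochondrially encoded transcripts were not lower and did not pass (9 of 15 higher, median 0.10, camera adjusted p = 0.151). Genes of the mitochondrial chromosome took 25.5%, 23.6% and 20.5% of the counts in shNC 1, 2 and 3. Their share was 26.0%, 26.1% and 27.3% in shYthdf2 1, 2 and 3. Genes of fatty acid oxidation were lower in 29 of 36 members (median -0.33, camera adjusted p = 0.0215) and those of the tricarboxylic acid cycle in 16 of 19 (median -0.22, adjusted p = 0.0353). Both had an adjusted p of 0.769 with an estimated correlation. Without shNC 2 both medians turned positive, to 0.08 and 0.12, and both calls were lost (adjusted p = 0.231 and 0.772). The fatty acid oxidation call was also lost without shNC 1, shYthdf2 2 or shYthdf2 3 (highest adjusted p = 0.333). The tricarboxylic acid cycle call was also lost without shNC 1, shYthdf2 1 or shYthdf2 2. Ventricular cardiomyocyte markers were lower in 25 of 32 members (median -0.34, camera adjusted p = 0.0027, and adjusted p = 0.769 with an estimated correlation). This call was lost without shNC 1, shNC 2 or shYthdf2 2 (highest adjusted p = 0.821). The member with the smallest p went the other way. Ttn, the giant sarcomere protein titin, had 811, 798 and 568 CPM in shNC and 1330, 1321 and 1983 CPM in shYthdf2. Myh6, the main adult ventricular myosin heavy chain of the mouse, had a log2 fold change of -0.63 ± 0.48 (SE).

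Erythroid and blood transcripts were lower in 10 of 10 members, with a median of -1.78 (camera adjusted p = 3.8e-08, and adjusted p = 0.761 with an estimated correlation). Adjusted over the list alone, 6 passed. The beta-globin gene Hbb-bs had 719, 1160 and 167 CPM in shNC and 211, 207 and 223 CPM in shYthdf2. Haemoglobin genes took 0.201%, 0.327% and 0.0533% of the counts in shNC 1, 2 and 3 and 0.0616%, 0.0613% and 0.0619% in shYthdf2 1, 2 and 3, so the excess lay in shNC 1 and 2. The call held at the preset correlation with any 1 library left out, with a median from -2.25 to -1.08, while the estimated correlation was 0.97.

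Matrix deposition and myofibroblast genes were higher in 32 of 39 members (median 0.27, camera adjusted p = 0.00032) and smooth muscle and pericyte markers in 10 of 17 (median 0.09, adjusted p = 0.0021). Both had an adjusted p of 0.761 with an estimated correlation. The members with the smallest p in the matrix list were Acta2 and Tagln, contractile genes of smooth muscle that both lists hold. In the smooth muscle list 2 members passed when adjusted over the list alone. Acta2 had 115, 92.8 and 128 CPM in shNC and 320, 321 and 174 CPM in shYthdf2. The matrix call was lost without shNC 2 (median -0.0071, adjusted p = 0.216) and the smooth muscle call without shNC 3 (adjusted p = 0.125). Over genes of at least 5 mean FPKM the smooth muscle median was -0.07.

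Cell cycle genes were higher in 30 of 34 members (median 0.44, camera adjusted p = 0.0021, and adjusted p = 0.769 with an estimated correlation). The list means were highest in shNC 3 (0.87) and shYthdf2 3 (1.28). Without shYthdf2 3 the median was -0.22 (adjusted p = 0.834), and the call was also lost without shNC 1 or shNC 2. Genes of cholesterol and lipid synthesis were higher in 23 of 27 members (median 0.34, camera adjusted p = 0.0022, and adjusted p = 0.761 with an estimated correlation). This call was lost without shYthdf2 3 (adjusted p = 0.217). Genes of the unfolded protein response were higher in 20 of 22 members (median 0.17, adjusted p = 0.0291), and cardiac stress and fetal genes in 13 of 22 (median 0.27, adjusted p = 0.0353). Each had an adjusted p of 0.769 with an estimated correlation. The medians of these 2 lists were -0.0024 without shYthdf2 3 and -0.16 without shNC 1. Both calls were lost without shNC 1, shNC 2 or shYthdf2 3 (highest adjusted p = 0.726 and 0.720). In the stress list Myh7, Nppa and Nppb had log2 fold changes of -0.06 ± 0.27, 0.27 ± 0.96 and 0.38 ± 0.94 (SE). Their signs turned for Myh7 with quantile normalization (0.079) and without shNC 3 (0.076), for Nppa without shNC 1 (-0.24) and for Nppb without shNC 2 (-0.10). At the other end, leaving out 1 library gave up to 2.36 for Nppa, and Nppb passed at 2.68 without shNC 3 (adjusted p = 0.0135). Interferon-stimulated genes were lower in 30 of 36 members (median -0.21, adjusted p = 0.0042, and adjusted p = 0.769 with an estimated correlation). This call was lost without shNC 1, shYthdf2 1 or shYthdf2 2 (highest adjusted p = 0.720).

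Among the ferroptosis lists, the promoting genes were higher in 22 of 32 members (median log2 fold change 0.10, camera adjusted p = 0.0291) and the transcript markers in 7 of 10 (median 0.20, adjusted p = 0.0388). Both had an adjusted p of 0.761 with an estimated correlation. The first call was lost without shNC 1, shNC 2 or shYthdf2 3 (highest adjusted p = 0.333) and the second without shNC 1, shNC 2, shYthdf2 1 or shYthdf2 2 (highest adjusted p = 0.257). Over genes of at least 5 mean FPKM the median of the promoting genes was -0.0073. Hmox1, the haem-degrading enzyme that both lists hold, was 2.37-fold higher (38.4, 23.4 and 75.5 CPM in shNC, 128, 124 and 73.6 CPM in shYthdf2, adjusted p = 0.976). Ncoa4, which directs ferritin to autophagy, had 10.1, 7.07 and 7.71 CPM in shNC and 7.42, 27.0 and 46.0 CPM in shYthdf2. Ptgs2, a prostaglandin synthase used as a ferroptosis marker, had 1.98, 0.811 and 15.1 CPM in shNC and 25.7, 28 and 4.22 CPM in shYthdf2. Its log2 fold change was 1.70 ± 1.10 (SE). With limma array weights, where 908 genes passed, Ptgs2 (log2 fold change 2.51, adjusted p = 0.0454) and Hmox1 (1.76, adjusted p = 0.0451) passed. Ferroptosis defence genes did not pass (20 of 32 higher, median 0.08, adjusted p = 0.212), nor did NRF2 targets (18 of 32 higher, median 0.13, adjusted p = 0.143). The same held for iron handling genes (12 of 29 higher, median -0.03, adjusted p = 0.889) and the m6A writers, erasers and readers (18 of 23 higher, median 0.12, adjusted p = 0.184). The NRF2 list passed without shYthdf2 3 and with the filter of any count. The log2 fold changes of Gpx4, the peroxidase that detoxifies lipid peroxides, of Acsl4, of the transferrin receptor gene Tfrc and of the ferritin gene Fth1 were -0.34 ± 0.27, 0.20 ± 0.31, -0.01 ± 0.40 and -0.09 ± 0.37 (SE). The signs of Tfrc and Fth1 turned under total-count scaling without mitochondrial and haemoglobin genes.

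**Figure D2:**
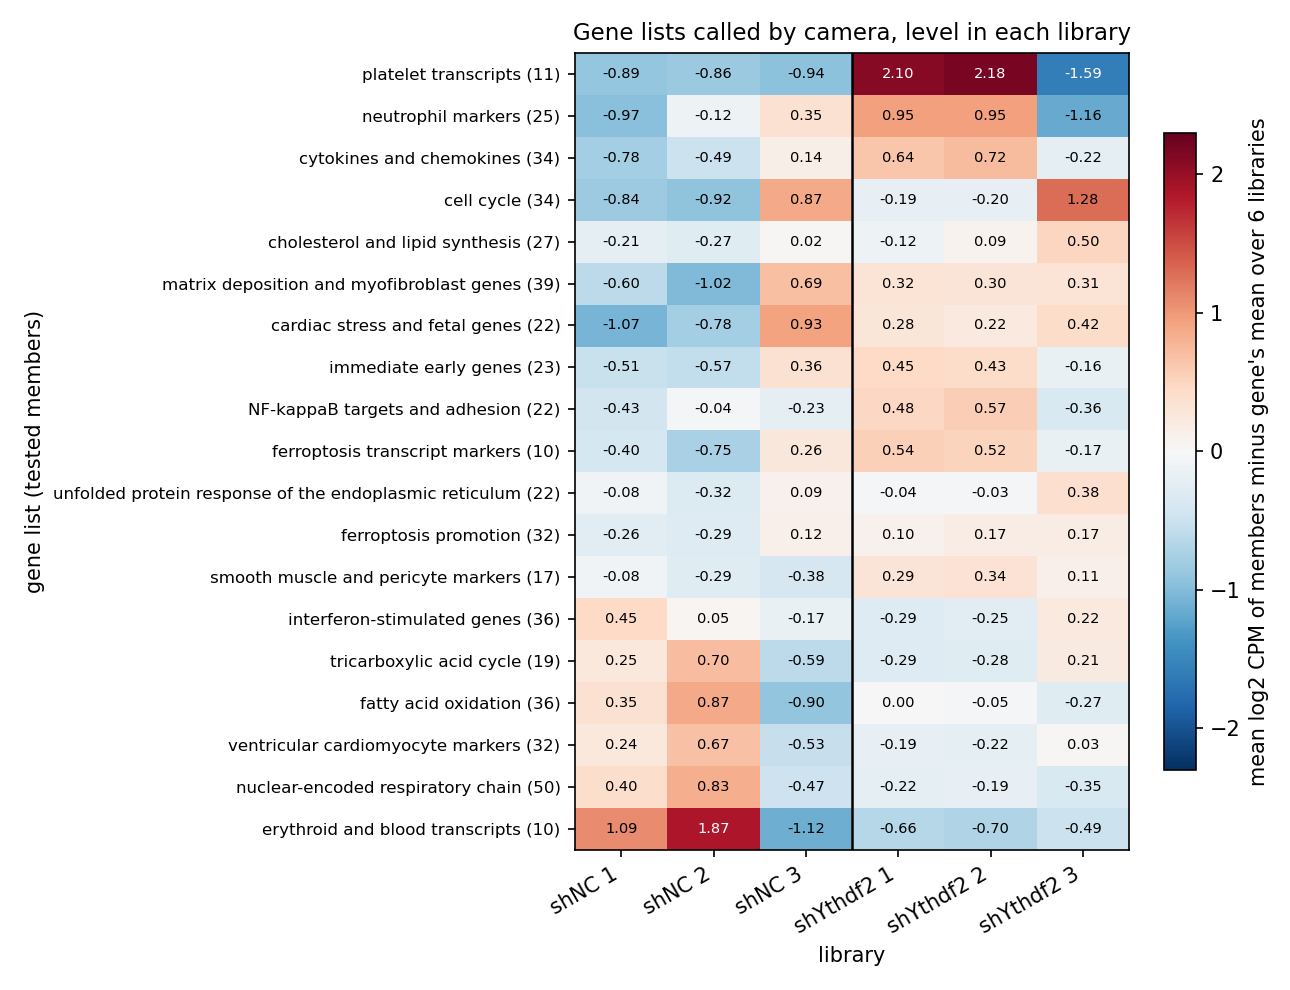
Mean log2 CPM of the members of each of the 19 gene lists past the camera threshold, in each library, less each gene's mean over the 6 libraries (colour scale in log2 units, tested members in brackets). Platelet transcripts reach 2.10 and 2.18 in shYthdf2 1 and 2 and -1.59 in shYthdf2 3, and erythroid transcripts 1.09 and 1.87 in shNC 1 and 2 and -1.12 in shNC 3.

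The libraries sorted by group only in part. By the biological coefficient of variation, shNC 1 was nearest to shNC 2 (19.4%). The library shYthdf2 3 was nearer to shYthdf2 1 and 2 (22.6% and 22.4%) than to any shNC library (25.5% to 31.7%). The exception was shNC 3, nearer to the shYthdf2 libraries (22.7% to 25.5%) than to shNC 1 and 2 (35.4% and 38.3%). The biological coefficient of variation between shYthdf2 1 and 2 was 13.6%, while every other pair of libraries had 19.4% to 38.3%, the highest being shNC 2 against shNC 3. The counts of shYthdf2 1 and 2 still differed beyond sampling noise (median chi-square per gene 4.95, where sampling alone gives 0.455), which does not show that they come from separate animals. They are treated as separate libraries, as labelled. Counts summed over these 2 libraries left 0 genes past the threshold in edgeR (409 at an unadjusted p under 0.05). The first principal component (34.1% of the variance) set shNC 1 and 2 (-66.2 and -91.6) apart from shNC 3 (97.9), with the shYthdf2 libraries between them, and the second (21.1%) set shYthdf2 3 apart (-103.7).

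**Figure D3:**
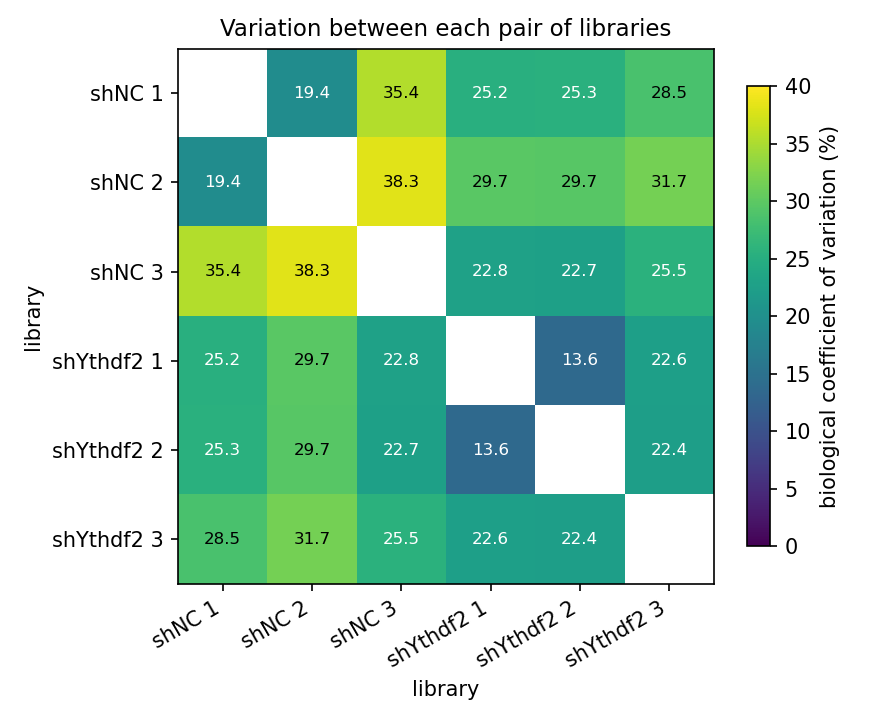
Biological coefficient of variation (percent, colour scale) between each pair of the 6 libraries, over well-covered genes. The pair shYthdf2 1 and 2 is lowest at 13.6%, and shNC 2 against shNC 3 is highest at 38.3%.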

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

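The alternatives limma with trend on log2(FPKM + 0.5), robust quasi-likelihood, shYthdf2 1 and 2 summed, and rows of one name summed were chosen only after the result was seen, and the others before. Ythdf2 was higher without passing in all 23 alternatives (log2 fold change 0.08 to 0.31), and Slc7a11 likewise in 22 (0.42 to 2.78). Kctd12 passed in 17 of 22 alternatives (adjusted p from 2.7e-25 to 0.491) and Eif4e in 12 of 23 (3.8e-30 to 0.491). Slc7a11 and Kctd12 are not among the genes of at least 5 mean FPKM. The number of genes past the threshold moved from 2 to 1 with limma on log2(FPKM + 0.1), on log2(FPKM + 1) and with trend on log2(FPKM + 0.5), to 3 with limma without trend and with robust empirical Bayes (Etv5 the added gene), to 1 with total-count scaling and with genes of at least 5 mean FPKM, to 0 with shYthdf2 1 and 2 summed (409 at an unadjusted p under 0.05), to 53 with DESeq2 and to 908 with array weights. Of the genes named without passing, 10 higher and 9 lower ones passed with DESeq2, 14 and 6 with array weights, and 7 and 2 without shNC 3. Leaving out 1 library gave 0 to 211 genes, with 464, 511 and 743 at an unadjusted p under 0.05 where shYthdf2 1, 2 or 3 was out and 0 passed. Both genes passed with any count, quantile normalization, median-of-ratios scaling and scaling without mitochondrial and haemoglobin genes. The 443 genes at an unadjusted p under 0.05 and at least 2-fold became 747 with any count, 62 at 5 mean FPKM, 666 with DESeq2 and 371 to 1657 without 1 library. With limma with trend on log2(FPKM + 0.5), which changes the test and the scale together, it was 137. From that value it moved to 127 without trend, 135 with robust empirical Bayes, 762 with array weights, and 389 and 92 at pseudocounts of 0.1 and 1. The 19 gene lists became 10 at 5 mean FPKM, 0 with the estimated correlation, 0 with the directional test of fry and 9 to 27 without 1 library. With limma on log2(FPKM + 1) the log2 fold change of the low gene Slc7a11 fell to 0.42, and fewer genes were tested at 5 mean FPKM. Eif4e lost its call with limma on log2(FPKM + 0.1) at a log2 fold change of 2.38, close to the 2.40 of the main fit. The cause of the changed counts of genes and lists was not tested.

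With the replicate block, 0 genes passed (628 at an unadjusted p under 0.05), 351 were in the 2-fold set and 18 lists passed. Libraries of the same number correlated at -0.01, -0.03 and -0.06 in their deviations from the group mean, which shows no pairing by number. With 3 libraries per group, and shYthdf2 1 and 2 much alike, these values cannot exclude a pairing. The labels do not state one. Whether the lost calls reflect weaker effects was not tested.

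Some named values changed sign. Fth1 was 0.078 with quantile normalization, 0.00076 with total-count scaling without mitochondrial and haemoglobin genes, 0.031 with array weights and -0.29 to 0.19 without 1 library. Tfrc was 0.0073 with any count, 0.026 with that scaling, 0.0014 with array weights, 0.21 with shYthdf2 1 and 2 summed and -0.50 to 0.35 without 1 library. Myh7 was 0.079 with quantile normalization, 0.11 with array weights, 0.046 with shYthdf2 1 and 2 summed and -0.25 to 0.076 without 1 library. Without 1 library Nppa ran from -0.24 to 2.36, Nppb from -0.10 to 2.68 and Ythdf1 from -0.0025 to 0.21. The median of iron handling was 0.026 with the same scaling and 0.063 with array weights, and -0.12 to 0.014 without 1 library. At 5 mean FPKM the median of smooth muscle and pericyte markers was -0.072 and that of ferroptosis promotion -0.0073. Without 1 library the medians ran from -0.0071 to 1.00 for matrix deposition and myofibroblast genes, -0.72 to 0.081 for fatty acid oxidation, -0.22 to 1.14 for cell cycle, -0.16 to 1.32 for cardiac stress and fetal genes, -0.53 to 0.12 for the tricarboxylic acid cycle and -0.0024 to 0.36 for the unfolded protein response of the endoplasmic reticulum. Of the other pairs of a named gene or list and an alternative, 1128 kept direction and side of the threshold, 90 lost a call and 52 gained one; the cause was not tested.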

Other observations

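The tests of the 3 patterns weighed here were all chosen only after the result was seen, while the splits of the libraries were planned. Among clock genes, the circadian list did not pass (8 of 19 higher, adjusted p = 0.621), but Arntl, which encodes the clock activator BMAL1, passed when adjusted over the list alone (1 member). It had 11.1, 8.50 and 9.50 CPM in shNC and 4.79, 3.98 and 3.89 CPM in shYthdf2. Npas2, a partner of BMAL1, had 3.62, 5.24 and 2.02 CPM in shNC and 1.30, 1.61 and 1.66 CPM in shYthdf2, and Clock had 35.8, 32.1 and 38.0 CPM against 31.0, 31.2 and 8.0 CPM. In the hypoxia list, which did not pass (14 of 25 higher, adjusted p = 0.163), Egln3, an oxygen-sensing prolyl hydroxylase, had 23.9, 23.4 and 18.8 CPM in shNC and 31.6, 33.4 and 46.3 CPM in shYthdf2. Of the 48 lists, fry's test for change in either direction called 1, the B and plasma cell markers (adjusted p = 0.00783). Of its members 7 of 16 were higher, and it did not pass camera (adjusted p = 0.280, and 0.769 with an estimated correlation) or the directional test of fry (adjusted p = 0.789). It holds Cr2, a complement receptor at 0, 0 and 0 CPM in shNC and 0.332, 0.168 and 0.224 CPM in shYthdf2.

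The natriuretic peptide genes, induced by wall stress, differed more among the shNC libraries than between the groups. Nppb had 171, 137 and 1951 CPM in shNC 1, 2 and 3 and 913, 898 and 1139 CPM in shYthdf2, and Nppa had 191, 503 and 3704 CPM against 1363, 1351 and 2593 CPM. Myh6 had 13840, 17236 and 4586 CPM in shNC and 7087, 6748 and 9211 CPM in shYthdf2. Macrophage and monocyte markers did not pass (21 of 33 higher, adjusted p = 0.125), and Arg1 among them had 31.4, 14.6 and 114 CPM in shNC and 148, 143 and 105 CPM in shYthdf2.

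Slc7a11 was at 10.8 and 12 CPM in shYthdf2 1 and 2 and at most 2.27 CPM in every other library. The tables argue against a larger share of RNA from macrophages as a whole. Of 33 macrophage and monocyte markers, 5 were higher in both than in all other libraries. Arg1 (148 and 143 CPM, at most 114 in the others) and Itgam (81.8 and 82.6 CPM, at most 77.3) were among these 5. A larger share of some macrophages therefore stays open. The tables argue against a larger share of neutrophil RNA as the whole cause only if expression per neutrophil was unchanged. The ratio of Slc7a11 to 21 of 25 neutrophil markers was higher in both. That ratio was higher too for 50 of 50 respiratory chain genes, 31 of 33 macrophage markers and 2 of 11 platelet transcripts. A high ratio is thus not particular to the neutrophil list. A larger share of neutrophil RNA as part of the cause stays open, since 15 of 25 neutrophil markers were higher in both, with a median gap of 0.377 log2 units. More platelets or clot in the tissue stays open as a candidate explanation, since 11 of 11 platelet transcripts were higher in both, although 1514 genes other than these and Slc7a11 (7.39%) also were, 10 of them with a gap at least as large as that of Slc7a11 (2.24 log2 units). An effect of the YTHDF2 shRNA stays open too, as 2 of 3 shYthdf2 libraries lay above all shNC libraries. These 2 libraries were the closest pair, and whether they share an animal or an RNA pool was not tested. Vkorc1l1, of the ferroptosis defence list, had the same pattern, with 0.554, 1.79 and 2.95 CPM in shNC and 17.8, 18.1 and 0.960 CPM in shYthdf2. Whether reads of Slc7a11 or Vkorc1l1 were counted on other rows in some libraries was not tested.

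Ythdf2 was not lower in the libraries labelled YTHDF2 shRNA. The lowest ratio of Ythdf2 means over the 20 assignments of these 6 libraries into 3 and 3 was 0.821. This argues against exchanged labels only for a knockdown to 0.5 or less in the whole tissue. With a smaller fall in the whole tissue the ratio cannot tell, and an exchange stays open. A fall in cardiomyocytes that is diluted by other cells may remain hidden. In the main fit the lower 95% bound of the ratio was 0.839, which leaves a fall of at most 16.1% in the whole tissue. That limit rests on all 6 libraries: the log2 fold change was 0.12 without shNC 1 and 0.08 without shYthdf2 3. No table here gives the share of Ythdf2 that cardiomyocytes hold. A knockdown at the protein level and an exchange with a library outside these 6 were not tested.

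Kctd12 and Eif4e were higher in all 3 shYthdf2 libraries. The table argues against reads counted on an overlapping row in the shNC libraries, where the rows that overlap them, Mir5130 and Mir1956, held at most 0.0922 CPM against the 32.2 and 60.6 CPM that would be needed. For Kctd12, all-or-none counts unrelated to the groups are a candidate explanation: of 9291 genes with at least 10 CPM in at least 3 libraries, 9 had 0 counts in some library, and in 7 of them the zeros did not follow the groups. Nnt and Adnp are among these 7, and a row overlapping each held counts in a library where it had 0. That was argued against for Kctd12, so not all of the 7 bear on it. Reads counted on a row elsewhere in the genome were not tested for Kctd12 or Eif4e. An effect of the shRNA was not tested apart from these explanations.

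Of the 10 splits of the 6 libraries into 3 and 3, 3, the real one included, gave at least the real count of genes past the threshold (2 genes, highest other 5). With the real one included, 4 gave at least its count of genes at an unadjusted p under 0.05 and at least 2-fold (443, highest other 1121), and 4 at least its count of lists (19, highest other 23). With 10 splits the share cannot go under 0.05. The split of shNC 1, shNC 2 and shYthdf2 3 against the rest gave 5 genes past the threshold, 1121 in the 2-fold set and 21 lists, which points to a structure of the samples other than the labels. An exchange of shNC 3 with shYthdf2 3 would give the same split, and it stays open, since the pairwise variation does not settle it. That of shNC 3 was lower with shYthdf2 1 and 2 (22.8% and 22.7%) than with shNC 1 and 2 (35.4% and 38.3%). That of shYthdf2 3 was also lower with shYthdf2 1 and 2 (22.6% and 22.4%) than with shNC 1 and 2 (28.5% and 31.7%). The exchange would not separate Ythdf2 either (20.7, 24.3 and 32.7 CPM against 25.1, 25.6 and 27.0 CPM).

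Overlapping rows differed between libraries in which of them held counts. Nnt, a mitochondrial transhydrogenase, had 5074, 30732 and 93 counts in shNC and 125, 219 and 26535 in shYthdf2 on one row (ENSMUSG00000025453), and 0, 0 and 9757 in shNC and 17659, 19498 and 0 in shYthdf2 on an overlapping row (ENSMUSG00000116207). Adnp had 4, 3843 and 0 counts in shNC and 4623, 42 and 4983 in shYthdf2, while the overlapping row Gm20716 had 6196, 0 and 317 in shNC and 0 in each shYthdf2 library, so in shYthdf2 2 and shNC 3 neither row held as many counts as in the other libraries.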
